A study of Mus musculus with 3 samples.

How the data were processed

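Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse induced regulatory T cells (iTreg cells), which are made in culture by activating CD4+ T cells in the presence of TGF-β. Per the labels' protocols, splenic CD4+ T cells of wild-type C57BL/6 mice aged 8 to 12 weeks were sorted and activated through CD3 and CD28 with TGF-β for 4 days before crosslinking. The labels list 3 libraries, which are a BACH2 ChIP, a JunD ChIP and an input, with 1 library per group. Peak lists of the 2 ChIP libraries were analysed. A signal file of the input was not used here. The labels' protocols give 2 catalogue numbers after the JunD antibody and do not say which of them gave the library.

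Reads were aligned with Bowtie 0.12.9 to mm9 (NCBIM37), per the submitters' processing notes. The peak caller's version, its control library and any pooling are not given in the sources used here. In the BACH2 list the authors deposited, each peak has a fold enrichment over the caller's background, a −log10 p-value, a −log10 q-value and a summit, as read from the narrowPeak layout. A further integer score in that deposited list equalled 10 times the −log10 q, cut to a whole number, in 100% of peaks, and was not used separately. In the JunD list the authors deposited, each peak has a start, an end and a single score, with peak names that begin with MACS, a peak caller. The scale of that score is not stated, and its lowest value is 50. The lists thus carry different scores, and BACH2 summits have no counterpart in the JunD list, where the centre of the peak was used. The score, fold and q-value are the authors' values for each peak and served only to rank or split peaks within their own list. The files hold no read counts, so the sequencing depth behind each peak is unknown, and there are no replicate libraries from which an error could be taken.

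All coordinates are mm9, the build the submitters' processing notes name, counted from 1. Peaks ran past the last gene of a GRCm38 gene table on 8 of 20 chromosomes, and no position from that table was used. Neither list pairs peaks with genes, and no mm9 sequence or annotation was used here. Peaks are therefore identified by position. The planned tests of genomic features, fixed gene lists, differences between factors in those lists, motifs and motif differences between peak sets, which needed mm9 genes or sequence, were not run.

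A peak was called overlapped when at least 1 bp was covered by a peak of the other list. Shares have Wilson 95% intervals, which cover the counting of peaks only. The overlap was tested with 1000 circular shifts. In each, all JunD peaks of a chromosome were moved by the same random distance, wrapping between the first and last peak position of the 2 lists, which keeps their widths and spacing. The two-sided p counts shifts at least as extreme, and the smallest p that 1000 shifts can give is 0.002. In the shifts, peaks can land where no peak would be called, so the comparison is with chromosomal positions in general and not with open chromatin. Strength was compared between overlapped and other peaks of 1 list by a permutation test over peaks with 100000 resamples, of the difference in median log2 −log10 q (BACH2) or log2 score (JunD), for which the smallest two-sided p is 2e-05. Peaks are not replicates, so these p-values concern positions and ranks within these 2 lists. Peaks were also split into quintiles by the authors' −log10 q (BACH2) or score (JunD), quintile 1 being the strongest.

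The rule for the peaks named, fixed before the data were examined along with the tests, took the 10 strongest peaks of each list and the 10 shared regions with the smallest sum of ranks. Other peaks, such as the widest, were picked after their values were seen. The alternatives changed the overlap required, the score threshold, the treatment of neighbouring peaks, the chromosomes, the kind of shift and the peak width. Two-sided tests were used throughout. The overlap procedure was tested on simulated data made from the 9133 BACH2 and 5237 JunD peak positions. With 0%, 5% and 20% of BACH2 peaks given an overlapping peak, it returned 0.197%, 5.27% and 20.5%, and with 200 shifts the p was 0.95 where no overlap was planted. The other JunD peaks of these simulated lists were placed by the same kind of shift. The check thus covers the counting of overlaps and not lists that crowd in the same regions. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.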

Results

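Binding sites of BACH2 and JunD were mapped by ChIP-seq in induced regulatory T cells. BACH2 is a transcriptional repressor of the basic leucine zipper family, and JunD is a subunit of the AP-1 transcription factor from the same family. Both bind DNA as dimers at related AP-1-like sequences, so the series sets their binding sites in the same cell type side by side. Each factor had 1 library, and no difference between the factors could be tested against replicate error. The depth of the libraries is unknown.

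The BACH2 list held 9133 peaks and the JunD list 5237, each spread over the 19 autosomes and the X chromosome. BACH2 peaks were narrow, with a median width of 267 bp (interquartile range 206 to 363 bp) and a maximum of 2113 bp. JunD peaks were broader, with a median of 553 bp (443 to 729 bp) and a maximum of 6491 bp. Widths over 1 kb were reached by 27 BACH2 peaks and 485 JunD peaks. In total, BACH2 peaks covered 2805 kb and JunD peaks 3379 kb. The fold enrichment of BACH2 peaks ranged from 1.43 to 57.6, with a median of 5.75 (4.41 to 8.05). Their −log10 q had a median of 11.8 and ran from 1.31 to 332. The JunD score had a median of 81.6 and ran from 50 to 2873. The lists were made with different scores, so neither their lengths nor their widths compare the number of sites bound by each factor.

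The strongest BACH2 peak lay on chromosome 19 from 5849740 to 5850590, with a fold enrichment of 57.6 and a −log10 q of 332.4. It was followed by peaks on chromosome 11 (60748771 to 60749489, 38.1-fold), chromosome 5 (116103010 to 116103627, 33.8-fold) and chromosome 13 (110566337 to 110566922, 27.7-fold). The fifth, also on chromosome 13 (113077215 to 113077904), had a fold enrichment of 41.1. The remaining members of the strongest 10 lay on chromosome 18 (38043071 to 38043623), chromosome 11 (116267542 to 116268271), chromosome 10 (18814068 to 18814790), chromosome 16 (87713104 to 87713969) and chromosome 8 (84280424 to 84281050), with enrichments between 21.0-fold and 31.4-fold. A JunD peak overlapped 3 of these 10, which were those at chromosome 19, chromosome 16 and 116267542 on chromosome 11.

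The strongest JunD peak covered 5286 bp of chromosome 11 (87568785 to 87574070) and had a score of 2873. Further members of the strongest 10 with widths over 4 kb lay on chromosome 11 (99004120 to 99008865), chromosome 1 (146090094 to 146096584), chromosome 5 (143663213 to 143667902) and chromosome 2 (11563935 to 11568153), with scores from 1136 to 1877. The other 5 all lay on chromosome 13, at 23830344 to 23832496, 23851762 to 23854626, 21871090 to 21872623, 23662050 to 23664390 and 21844551 to 21847179. These lay within 2.01 Mb, a stretch that held 36 JunD and 50 BACH2 peaks. A BACH2 peak overlapped all 10. The strongest BACH2 peak in each was in the strongest BACH2 quintile in 2 of the 10 and in the weaker 50% of the list in 4.

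**Figure D1:**
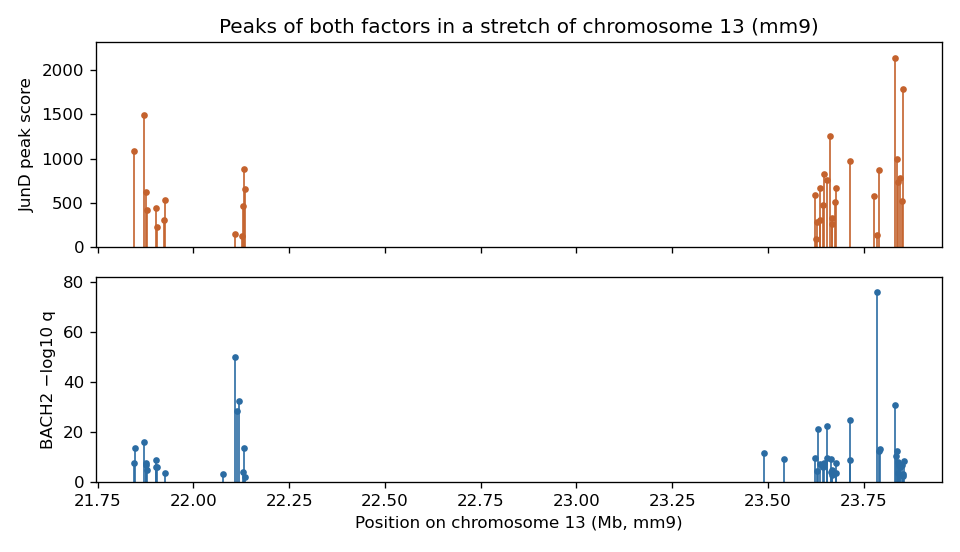
JunD peak score (upper panel) and BACH2 −log10 q (lower panel) of each peak, drawn as a line with a dot at the peak's middle, by position on chromosome 13 (x axis, Mb, mm9) from 21844551 to 23854626. Of the 25 strongest JunD peaks, 12 lay here, and the median BACH2 peak of the stretch had a −log10 q of 7.71.

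The first comparison asked how far the binding sites of the factors coincide. A JunD peak overlapped 2674 of the 9133 BACH2 peaks, or 29.3% (95% interval 28.4 to 30.2), and the remaining 6459 were BACH2-only. A BACH2 peak overlapped 2557 of the 5237 JunD peaks, or 48.8% (47.5 to 50.2), and 2680 were JunD-only. Shifted positions gave a mean of 0.211% for BACH2 peaks and 0.363% for JunD peaks, so the observed overlaps were 139 and 135 times as frequent (permutation of positions, p = 0.002 for each, the smallest that 1000 shifts can give). The highest share in any shift was 0.449% for BACH2 and 0.745% for JunD. When each JunD peak was instead moved by 10 to 100 kb, which keeps it in its neighbourhood, the mean share was 1.02% for BACH2 and 1.72% for JunD, and the observed overlaps were 28.8 and 28.3 times as frequent (permutation p = 0.002 for each). The size of the share depended on the overlap required, since asking for 50% of both peaks lowered it to 15.3% of BACH2 and 26.6% of JunD peaks, and asking for 50% of the JunD peak alone gave 27.0% of JunD peaks. Asking for 50% of the BACH2 peak alone gave 28.8% of BACH2 peaks. JunD peaks were wider (median 553 against 267 bp), so even a well-centred BACH2 peak can be too narrow to cover 50% of a JunD peak.

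Within shared regions the BACH2 summit lay close to the middle of the JunD peak. Over the 2677 overlapping pairs the median distance from the BACH2 summit to the JunD centre was 55 bp (interquartile range 24 to 121 bp). The distance was at most 50 bp in 46.7% of pairs, at most 100 bp in 70.2% and at most 500 bp in 97.3%. Only overlapping pairs were measured, so peak widths limit these distances, and the share within 500 bp was largely set by that. The summit fell inside the JunD peak in 2633 pairs. In these, the median distance was 0.183 of the way from the centre to the edge, against 0.5 for summits placed evenly along the JunD peak (permutation test with 10000 random placements, p = 0.0002, the smallest they can give). Most shared JunD peaks, 2447, held 1 BACH2 peak, while 104 held 2 and 6 held 3 or more. BACH2-only peaks also lay nearer to JunD peaks than shifted positions did, with a median distance of 47.1 kb from summit to the nearest JunD centre against a mean of 419 kb over the shifts (permutation p = 0.002). Of these BACH2-only peaks, 2.68% had a JunD centre within 1 kb. The shifts ran over whole chromosomes, and no local shift was tried for this distance. It therefore does not separate closeness of sites from a tendency of both lists to crowd in the same regions.

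**Figure D2:**
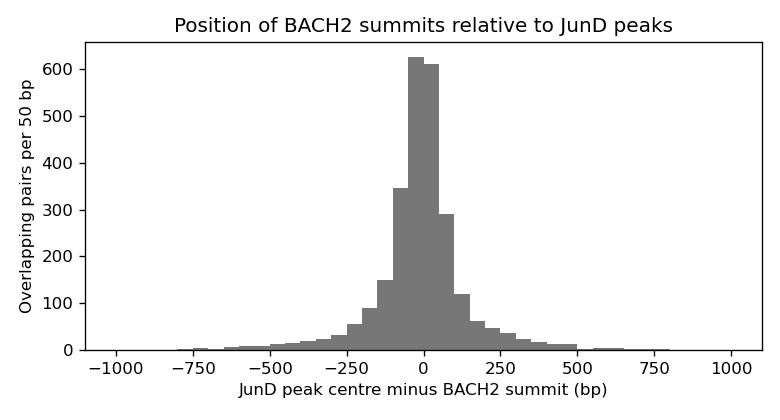
Number of overlapping BACH2 and JunD peak pairs (y axis, pairs per 50 bp) by the distance from the BACH2 summit to the JunD peak centre (x axis, bp), drawn between −1000 and 1000 bp. The pairs gather around 0, with a median absolute distance of 55 bp.

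The second comparison asked whether overlap depended on the strength of a peak. Of the BACH2 peaks, 42.9% (40.7 to 45.2) of the strongest quintile by −log10 q were overlapped by JunD, against 32.6%, 25.8%, 22.1% and 23.1% in quintiles 2 to 5. Of the JunD peaks, 67.8% (65.0 to 70.6) of the strongest quintile were overlapped by BACH2, and the share was lower in each weaker quintile, down to 33.1% (30.4 to 36.1) in the weakest. The median −log10 q was 15.7 in shared and 10.9 in BACH2-only peaks, a log2 difference of 0.54 (permutation test over peaks, p = 2e-05, the smallest possible). The median JunD score was 96.9 in shared and 72.7 in JunD-only peaks, a log2 difference of 0.41 (permutation test over peaks, p = 2e-05). Shared peaks were also wider, with medians of 318 against 251 bp for BACH2 and 594 against 520 bp for JunD. The fold enrichment of BACH2 peaks had a median of 5.91 (interquartile range 4.30 to 9.03) in shared and 5.69 (4.44 to 7.74) in BACH2-only peaks, a log2 difference of 0.056 (permutation test over peaks, p = 0.0006). These medians hide a relation that is not steady, because overlap was most frequent at both ends of the fold range, at 37.1%, 26.6%, 25.4%, 24.8% and 32.5% from the highest to the lowest quintile of fold. Fold and −log10 q are different scales, so their log2 differences are not compared in size.

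**Figure D3:**
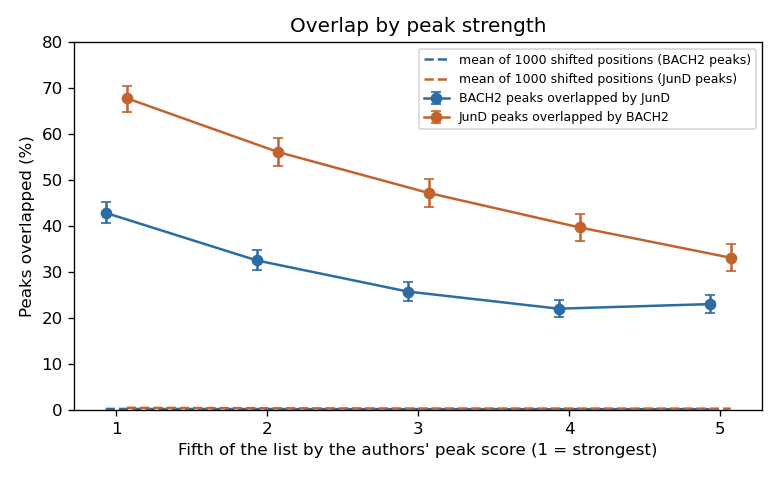
Share of peaks overlapped by the other factor (y axis, percent) in quintiles of each list by the authors' score (x axis, 1 is the strongest), BACH2 peaks in blue and JunD peaks in orange. Bars are Wilson 95% intervals and dashed lines are means of 1000 shifts, which stay below 0.5% in both lists.

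Strong peaks without the other factor were found in both lists, though less often than among all peaks. In the strongest BACH2 quintile, 1043 of 1827 peaks (57.1%) had no JunD peak, against 6459 of 9133 in the whole list. The 5 strongest of them were the peaks ranked 2 to 6 described above, on chromosomes 11, 5, 13 and 18. In the strongest JunD quintile, 337 of 1048 peaks (32.2%) had no BACH2 peak, against 2680 of 5237 in the whole list. The strongest JunD-only peaks lay on chromosome 6 (51407463 to 51410835, score 818), chromosome 5 (22937847 to 22940097, score 775) and chromosome 17 (36054286 to 36056849, score 744). They ranked 19, 22 and 27 in the JunD list.

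At shared regions the strengths of the factors were only weakly related among peaks that passed both callers' thresholds. Across the 2557 shared JunD peaks, each paired with its strongest BACH2 peak, Spearman's rho between JunD score and BACH2 −log10 q was 0.09 (permutation p = 2e-05) and Pearson's r of their logarithms was 0.07 (permutation p = 0.0005). These are correlations across peaks, which are not independent replicates. They cover only overlapping peaks above both thresholds, which narrows the range of both scores. For the 2259 pairs with a JunD peak up to 1 kb wide, Spearman's rho was 0.12. With BACH2 fold in place of −log10 q, rho was 0.036. Both peaks were in the strongest quintile of their list in 258 regions, against 218 if the ranks were unrelated. The strongest BACH2 peak of all met a JunD peak of score 75.5, which ranked 2951 of 5237.

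**Figure D4:**
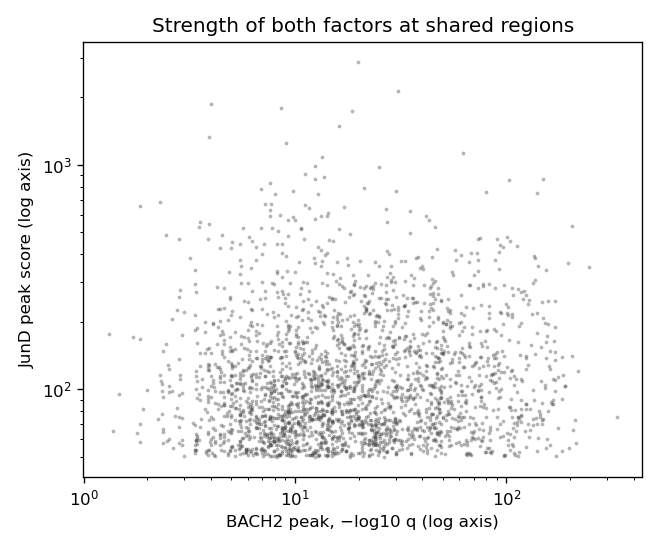
JunD peak score (y axis, log scale) against the −log10 q of the strongest overlapping BACH2 peak (x axis, log scale) for the 2557 shared JunD peaks, one point per JunD peak. The points form a broad cloud with a Spearman's rho of 0.09.

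The shared region with the smallest sum of ranks in the 2 lists lay on chromosome 12, where a BACH2 peak (74942986 to 74943778, 24.9-fold, rank 15) met a JunD peak of score 535 (rank 60) with 69 bp between summit and centre. On chromosome 8, a BACH2 peak at 129391410 to 129392010 (17.6-fold) met the JunD peak ranked 16, with a score of 866, and another at 89380199 to 89380663 (24.5-fold) met a JunD peak of score 364. A BACH2 peak on chromosome 4 (32336711 to 32338352, 18.9-fold), 1642 bp wide and among the widest of its list, coincided with a JunD peak of score 750. The remaining 6 regions lay at 116267542 on chromosome 11, 3280755 on chromosome 18, 8132261 and 66310803 on chromosome 17, 4992954 on chromosome 19 and 33273353 on chromosome 5, each given by the start of its BACH2 peak. In these 10 regions, the distance between BACH2 summit and JunD centre was between 2 and 305 bp.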

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

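The tests of JunD peaks over 2 kb left out and of chromosome 13 left out were chosen after the data were seen. Under all 13 alternatives the overlap stayed above the shifted positions with a permutation p of 0.002. The share of BACH2 peaks ranged from 15.3% to 42.9% and that of JunD peaks from 26.6% to 67.8%. The upper ends came from the strongest quintile of each list, which is a subset of its peaks. Keeping only the strongest 4566 BACH2 and 2618 JunD peaks gave lower shares than the full lists, 22.3% and 38.2%. The size of the share thus also depended on the score threshold. The ratio of the overlap to the shifted mean ran from 28.8 and 28.3 (each JunD peak moved locally) to 463 (summit or centre within 100 bp). With equal numbers of strongest peaks, 34.0% of BACH2 and 33.4% of JunD peaks were shared, values that are nearly equal by construction because most overlaps join 1 peak of each list. Setting every peak to 200 bp gave 25.1% and 43.7%. Leaving out the 51 JunD peaks wider than 2 kb gave 28.7% and 48.7%, and leaving out chromosome 13 gave 28.9% and 48.2%. The strength difference between shared and other peaks kept its direction under the alternatives tried, and for BACH2 it was 0.54 on the log2 −log10 q scale and 0.056 on the log2 fold scale, values that are not comparable in size because the scales differ. At 200 bp it was 0.60 for BACH2 and 0.30 for JunD. The median distance from summit to centre was 55 bp, and 51 bp between peak centres. No paired analysis was possible because each group had 1 library. Alternatives for genomic features, gene lists and motifs were not run. Sites below the callers' thresholds are not in the lists, and the depth that set those thresholds is unknown.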

Other observations

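The tests of crowding, of the chromosome 13 stretch, of fold quintiles and of strong BACH2 peaks without JunD were chosen after the main results were seen. BACH2 peaks often came in groups. Joining peaks at most 10 kb apart gave 6690 BACH2 regions, of which 1528 held 2 or more peaks and 94 held 5 or more. JunD overlapped 23.6% of single BACH2 peaks, 36.7% of those in regions of 2 or more and 45.2% of the 569 in regions of 5 or more. For JunD peaks grouped the same way, BACH2 overlapped 47.4%, 51.4% and 44.4% (of 358 peaks), with no steady direction. These shares were not tested. Outside chromosome 13, the largest BACH2 groups held 11 peaks each, on chromosome 2 (11538509 to 11585948, 9 of them overlapped) and chromosome 7 (82716918 to 82757405, 6 overlapped). The same region of chromosome 2 held a group of 11 JunD peaks, 8 of them overlapped. A region of chromosome 15 (66609700 to 66645992) held 11 JunD peaks, of which only 3 were overlapped.

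The X chromosome had few peaks of either factor. It held 142 BACH2 and 62 JunD peaks, or 0.867 and 0.379 per Mb up to its last peak, against autosomal medians of 3.60 (range 2.80 to 5.78) and 2.02 (1.28 to 3.93). Read coverage of the X chromosome is unknown, so these densities do not give the number of sites bound there. The share of BACH2 peaks overlapped was 19.7% on X (14.0 to 27.0) and 29.4% on the autosomes. The median −log10 q of BACH2 peaks was 10.3 on X and 11.9 on the autosomes, and their median fold enrichment was 6.12 and 5.75. The share of JunD peaks overlapped was 45.2% on X (33.4 to 57.5) and 48.9% on the autosomes. A JunD peak of 6054 bp on chromosome 17 (39979795 to 39985848) was the third widest of its list. The strongest BACH2 peak that overlapped this JunD peak had a fold enrichment of 2.02, below the list median of 5.75. Its −log10 q was 13.3, above the list median of 11.8. No filter for regions prone to artefact signal was applied here to either list.

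The strongest JunD peaks were concentrated in a stretch of 2.01 Mb on chromosome 13 (21844551 to 23854626), which held 12 of the 25 strongest but only 36, or 0.687%, of all JunD peaks. Of these 36, 30 were overlapped by BACH2. The 12 defined the stretch, and of the other 24, 21 were in the strongest quintile. The 24 are neighbours of the 12, so they are not a check free of that choice. Peak width alone does not account for the scores of these 24, since among the 100 JunD peaks of most similar width elsewhere their median percentile was 91 (interquartile range 80.2 to 96.2). A signal common to both ChIPs stays open. BACH2 peaks were also 6.55 times as dense there as on the rest of chromosome 13, and JunD overlapped 39 of these 50, against 29.3% of the whole list. Because strong JunD peaks defined the stretch, that high share is partly set by the choice. JunD peaks there were dense (17.9 per Mb against 1.84 on the rest of chromosome 13). They were also wide, with a median of 1580.5 bp against 553 bp in the whole list. Yet the median fold of the 50 BACH2 peaks was 4.53 and their median rank was 69.4% of the way down the BACH2 list (bootstrap 95% interval 60.2 to 75.8). These are neighbouring peaks of 1 library, so the interval does not cover variation between libraries. The ranks of the factors come from different scores. No biological explanation was tested.

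BACH2 peaks with the lowest fold enrichment met JunD peaks more often than those of middle fold. By quintile of fold, from highest to lowest, the share overlapped was 37.1%, 26.6%, 25.4%, 24.8% and 32.5% (30.4 to 34.7 in the last). A few crowded regions do not account for this, since outside chromosome 13 and regions of 5 or more BACH2 peaks the lowest quintile still had 30.2% (28.0 to 32.5) against 23.8% (21.8 to 25.9) in the fourth. A candidate explanation is a high local background at these peaks, because at a given fold a larger −log10 p means more reads. In the lowest quintile, the peaks with the larger −log10 p at matched fold were overlapped 1.74 times as often (41.2% against 23.7%). The same split gave larger ratios, 1.80 to 3.29, in the other quintiles. The explanation called for the largest ratio in the lowest quintile, but that ratio was the smallest, so the relation is not special to low-fold peaks. The peaks with the larger −log10 p were also wider in every quintile (median 231 against 196 bp in the lowest, 343 against 254 bp in the second), and shared BACH2 peaks were wider than BACH2-only peaks in the whole list. The split therefore does not separate background from peak strength and width, and this explanation is left open. Whether the reads come from open chromatin in the cells or from the procedure was not tested.

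Of the strongest BACH2 quintile, 1043 peaks had no JunD peak. Near misses do not account for them, since 2.21% had a JunD peak within 500 bp. The JunD threshold may account for part of them and stays open. The share of JunD peaks that met a strongest-quintile BACH2 peak fell with JunD strength, from 24.6% to 17.2%, 14.2%, 11.5% and 7.45%, and the weakest JunD quintile added 4.27 percentage points to the BACH2 peaks met, against 6.51 for the quintile above it and at most 0.109 in the middle 95% of shifted positions. How many would be met below the threshold cannot be read from the list. A BACH2-specific set of sites, as a biological difference between the factors, stays open and was not tested.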
